A study of Camellia sinensis with 2 samples.

How the data were processed

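Degradome tags of tea were analysed from 2 libraries, 1 of leaf and 1 of root, as the tissue labels give them. Per the labels' protocols, total RNA was isolated with TRIzol and libraries were made by a standard Illumina procedure in which rRNA was removed. The values are counts as deposited: whole reads per distinct tag sequence, per the file headers and the values. Adapter trimming, filters, aligner and any mapping are not given in the sources used here.

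Each list was 1 alphabetical series of tags wrapped over column pairs, 5 for leaf and 8 for root, all of which were used. All tags had 20 bases, none was listed more than 1 time and the lowest count was 1. Some lines had been emptied before this work, 5452 of 1000000 (0.545%) for leaf and 9627 (0.963%) for root, each with 1 tag per column pair; those tags were not analysed here. The root list has no tag in 1 stretch of the alphabet within AAT, the largest step between its neighbouring tags. All 8 root column pairs were filled to the last line, and whether further tags are missing was not determined. In leaf that stretch holds 57928 tags (1.19%) and 176709 reads (0.929%). Tags there could not be compared, and root RPM are relative to the listed reads.

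No transcript sequences were used, and the gene table at hand gives names without sequences, so tags were not matched to genes and the gene lists fixed beforehand were not tested. Target names are background from other plants. A panel of 39 miRNAs, 34 of them widely conserved in 31 families (1 of these, tasiARF, is a trans-acting siRNA treated alike) and 5 known from the cabbage family as lineage controls, was written before the data were examined, as were the main comparisons and most alternatives.

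A cut opposite miRNA nucleotide 10 gives a tag whose first 10 bases pair with nucleotides 1 to 10. The 10 bases upstream were taken from other tags of either library, which start up to 14 bases upstream and were reached by overlaps of at least 15 bases, or start exactly 10 bases upstream with an overlap of 10. A mismatch cost 1 and a G:U pair 0.5, doubled at miRNA nucleotides 2 to 13, and the sum over nucleotides 1 to 20 was at most 4. A called site had at least 10 reads and the highest count among tags that start within 10 nucleotides either side and share all overlapping bases. At an overlap of 10 bases a tag of another transcript can count as a neighbour or as upstream sequence. For the position profile, words of 10 bases came from tags that span a site with score at most 4, or else from all words with a score of at most 1; reads of tags in which the word began at the first base were set against the mean of the 9 next starts. Each miRNA was shuffled 100 times with its dinucleotides kept, and the rank of the real value describes these libraries only.

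RPM stands for reads per 1000000 listed reads of a library. Ratios used called sites of either library, with exact conditional binomial intervals at 95%, and shares used exact Clopper-Pearson intervals; a library at 0 was set to 3 reads for ranking tags. There is 1 sample per group, so no test across samples was made. Named items are, by a rule fixed beforehand, every family with at least 10 reads at the expected position of its best site, the 5 most abundant tags of each library, and the 10 tags with the largest ratio each way among those with at least 100 reads in 1 library. Tags with no match among the marker sequences, which could belong to other organisms, are given by count alone. Marker sequences (rRNA starts, plastid transcripts, adapters) were written from general knowledge after the most abundant tags had been seen.

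The search was tested on simulated data: sites of made-up miRNAs were planted among the real tags, 50 for each leaf over root fold. Tags upstream of every planted site were added to both libraries, so its upstream bases could be found. Real sites can lack such tags, so the counts called here do not measure how many real sites were missed. At fold 4, 50 were called in leaf and 49 in root, and 41 of 50 intervals held the planted fold; 4 of the 9 that missed included another tag. At fold 1, 50 and 49 were called and 47 intervals held it, and at fold 0.25, 42 and 48 with 47. Of 50 made-up miRNAs without a site, 0 were called in leaf and 1 in root. Alternatives covered the score limit, read minimum, window, counting of tags, thinning to the same number of reads, and the scaling of libraries. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9 were used.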

Results

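Degradome tags were read from 1 leaf library and 1 root library of tea, Camellia sinensis, an evergreen shrub grown for its leaves. A degradome library captures the 5' ends of cut or decaying RNA, so each tag marks the base at which a fragment begins. The question, per the series title, was which transcripts are cut under the guidance of microRNAs (miRNAs) in different organs. The leaf list held 19012687 reads over 4888039 distinct 20-base tags, and the root list 16087489 reads over 7922984 tags. With 1 library per organ no difference has a replicate check. The 95% intervals below are exact binomial intervals, or exact conditional binomial intervals for ratios, and cover counting error only, since reads multiplied by PCR are not independent molecules.

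The 4 most abundant tags of the leaf library began at the mature 5' ends of ribosomal RNA (rRNA), or 1 base inside for plastid 23S rRNA. The rRNA stretches among the marker sequences took 18.9% of leaf reads against 0.756% of root reads. These stretches cover only parts of the rRNA and include fungal-type ones, so the shares are not those of all rRNA. In leaf the most abundant tag was TCAAACGAGGAAAGGCTTAC, of plastid 23S rRNA, with 1306106 reads against 3983 in root. The 18S rRNA start tag TACCTGGTTGATCCTGCCAG followed with 963203 leaf reads and 41504 root reads. The 25S rRNA start tag GCGACCCCAGGTCAGGCGGG had 691253 and 59610, and the plastid 16S rRNA start tag TCTCATGGAGAGTTCGATCC had 530981 and 1534. The plastid, the photosynthetic organelle of green tissue, carries its own ribosomes. The fifth tag of both libraries, CCCTACACGACACAAATCAA, had 202594 reads in leaf and 25830 in root and begins with bases of a sequencing adapter. In root the 25S start tag ranked first, a run of A bases second with 55476 reads (153065 in leaf), the 18S start tag after it, and a tag with no match among the marker sequences next with 37952 reads (3864 in leaf).

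The 5 most abundant tags held 19.4% of leaf reads and 1.37% of root reads, and the 100 most abundant held 25.2% (25.2 to 25.3) and 2.69% (2.68 to 2.70). Root fragments were spread over more ends, with 2.03 reads per distinct tag against 3.89 in leaf and 65.7% of tags seen once against 49.9%. T was the first base of 35.4% of leaf reads and 25.3% of root reads, and A of 25.2% and 33.7%. The plastid 23S, 18S and plastid 16S start tags all begin with T. They alone held 6.87%, 5.07% and 2.79% of leaf reads, against 0.0248%, 0.258% and 0.00954% of root reads. Over distinct tags the shares lay closer, at 28.4% and 26.2% for T. In RPM, reads per 1000000 listed reads of a library, 1 read was worth 0.0526 in leaf and 0.0622 in root. A tag with 0 reads allows up to 0.158 and 0.186 RPM, unless it stood in an emptied line, where its count is unknown. The same limit holds for every tag given below at 0.

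Most distinct tags were listed in 1 library alone, though a tag seen once leaves open whether the other organ has it. The libraries had 1107564 tags in common, which made 22.7% (22.62 to 22.70) of leaf tags and 13.98% (13.96 to 14.003) of root tags. These shared tags carried 56.1% (56.1 to 56.2) of leaf reads and 31.2% (31.2 to 31.2) of root reads. With both libraries at 16087489 reads the shares of tags were 23.2% and 13.1%. Of 8841 tags with at least 100 reads in 1 library, 1445 had no read in root, beyond 63 that fell where the root list has none, and 706 had no read in leaf. The 10 with the largest ratio towards leaf had 1224 to 10201 leaf reads and were 933 to 2877 times higher, 2 of them at 0 in root and counted there as 3 reads; 1 of the 10 holds adapter bases and the rest matched no marker sequence. The 10 with the largest ratio towards root had 969 to 4757 root reads and were 1145 to 5622 times higher, with 1 at 0 in leaf, and none matched a marker sequence.

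Over the conserved panel as a whole, reads were in excess at the position where an Argonaute protein cuts, opposite miRNA nucleotide 10. In leaf, 8728 reads began there, against a mean of 3335 (3066 to 3626) at each of 9 other starts over the same words, a ratio of 2.62 (2.56 to 2.68). Root had 8758 reads there against a mean of 3847 (3717 to 4173), a ratio of 2.28 (2.22 to 2.33). The same ratio over miRNAs known from the cabbage family was 0.861 in leaf and 0.850 in root. Of 100 panels of dinucleotide-shuffled miRNAs none reached the real ratio in either library; they gave medians of 0.903 and 0.948 and at most 1.84 and 1.98. The excess lay in the reads of a few tags, since counting each distinct tag once gave 0.884 in leaf and 0.914 in root, both below 1.

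By family, the excess at the expected position depended on the words searched, which came from tags that span a site where such tags were found and otherwise from all matches to the first 10 bases. With words of spanned sites the leaf ratio was above 3 for miR858 at 31.1 times the other starts (27.6 to 35.2), miR393 at 18.8, miR164 at 18.1, miR172 at 9.73, miR156 at 8.86, miR167 at 8.002 and miR169 at 3.57. With the first 10 bases it was above 3 for miR166 at 18.8, miR160 at 6.43 and miR828 at 5.82. In root the spanned ones were miR164 at 43.0 (39.3 to 47.1), miR156 at 7.06, miR393 at 6.89 and miR396 at 3.11, and the others miR166 at 11.6 and miR160 at 5.68. Of 31 families, 10 in leaf and 8 in root exceeded all 100 of their own shuffled versions. The 10 leaf families include miR171 at 2.14 but not miR828, as 1 shuffled version did at least as well, and the 8 root families include miR169 at 2.19 and miR319 at 1.697.

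With the first 10 bases searched for every miRNA the counts were 11 and 5, and ratios moved in both directions. In leaf miR858 fell to 11.5, miR393 to 6.12, miR164 to 4.74, miR156 to 3.27, miR172 to 2.94 and miR167 to 0.763, while miR403 rose from 0.867 to 5.59 and tasiARF from 1.62 to 3.895, of whose 2399 reads at the expected position 1 tag gave 1924. In root miR164 fell to 15.4, miR156 to 2.58, miR393 to 2.41 and miR396 to 1.09, while miR403 rose from 1.401 to 3.43. By either search, miR159, miR162, miR390, miR398, miR399, miR408, miR530, miR535, miR827, miR2111, miR2950 and the family of miR482 and miR2118 did not exceed all their shuffled versions in either library. Nor did miR168, miR394, miR395, miR397 and miR828, although miR168, miR395 and miR828 are among the families with a called site below.

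**Figure D1:**
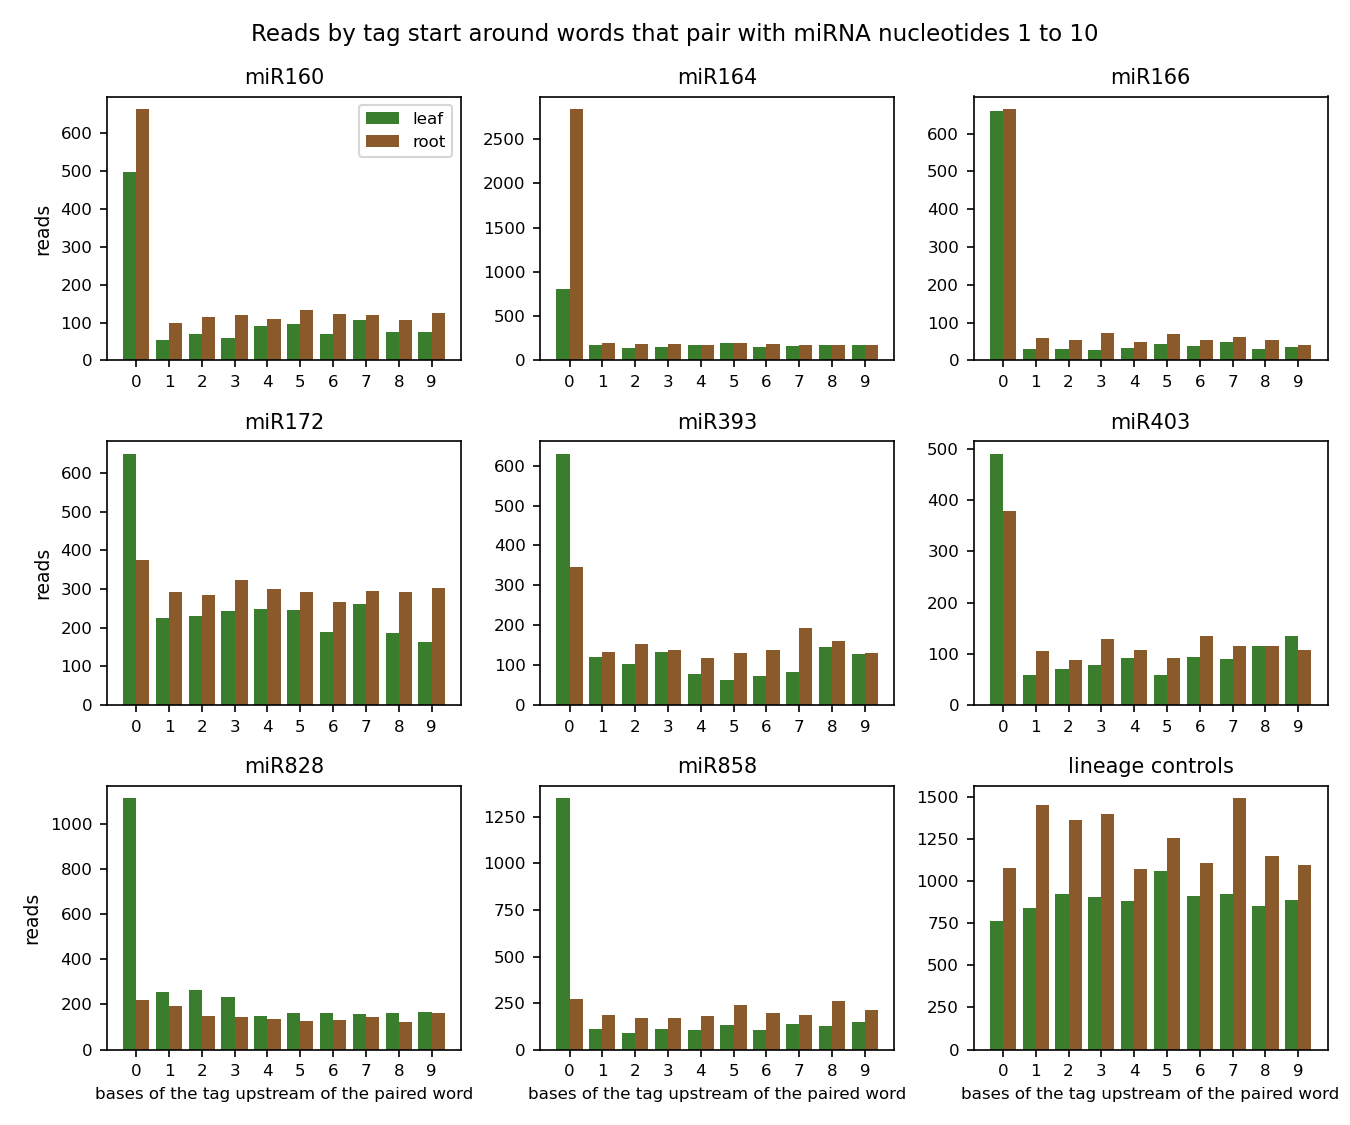
Reads (vertical axis) by the number of tag bases upstream of a 10-base word that pairs with miRNA nucleotides 1 to 10 (horizontal axis; 0 is the expected cut), for 8 families and the pooled lineage controls, with leaf in green and root in brown, for words with score at most 1. The bar at 0 stands above the other starts in the families shown, with miR828 and miR858 far higher in leaf and miR164 far higher in root, and not in the controls. The 8 families were picked for display, and others with and without such an excess are not shown.

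Cut sites that paired over miRNA nucleotides 1 to 20 were called for 14 of 31 families in leaf and 13 in root, with the same 13 in both and miR828 in leaf alone; with a window of 5 nucleotides miR828 was called in root too. A call needed at least 10 reads at the expected position, the highest count within 10 nucleotides either side and a pairing score of at most 4. None of the 5 lineage controls was called in either library. The shuffled panels gave a mean of 1.47 families in leaf and 1.30 in root, and 5 at most in each. The sites of miR319, miR395 and miR167 scored 4, the limit. At a score of at most 3, 10 families were called in leaf and 8 in root, with miR828 and miR858 in leaf alone, against a shuffled mean of 0.25 and 0.18.

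**Figure D2:**
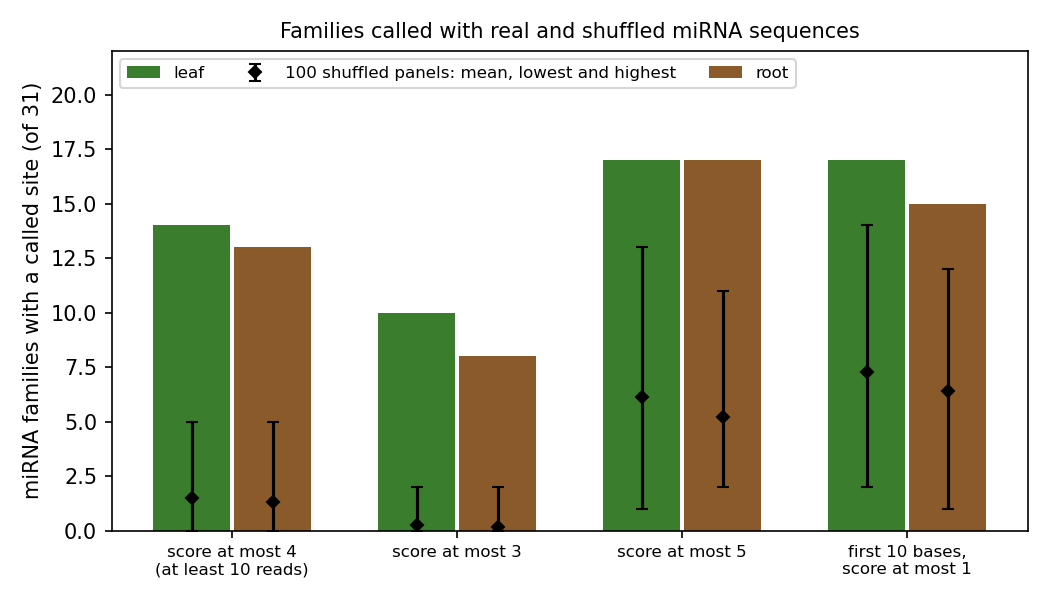
Number of miRNA families with a called site (bars; leaf green, root brown; vertical axis from 0) under 4 site definitions, with the mean, lowest and highest of 100 shuffled panels (diamonds and whiskers). At a score of at most 4 the bars stand at 14 and 13 and the shuffled panels reach 5 at most.

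Towards leaf, the largest ratios were those of 2 families whose known targets in other plants include R2R3-MYB factors. Such factors regulate flavonoid and phenylpropanoid synthesis, the pathway of tea catechins, but the tags here were not matched to genes. The miR828 site tag TTGAGCAAGAAAATAAATCA had 856 reads in leaf and 25 in root, where it was not the highest count in its window, an RPM ratio of 28.97 (19.5 to 45.02). The 4 miR858 sites summed to 1166 leaf reads and 60 root reads, a ratio of 16.4 (12.7 to 21.7), led by AGACAATGAAATCAAAAACT with 396 against 6 and AGACAATGAAATCAAGAACT with 357 against 3. Another miR858 site, AGACAATGAAGTGAAGAACT, had 216 against 46 reads, a smaller ratio of 3.97 (2.88 to 5.59).

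Root was higher for miR396 and miR164. The miR396 tag AGCTATGGAGGTCACACATT had 531 reads in root and 24 in leaf, 26.1 times more RPM in root (17.4 to 41.2). The score of that site was 3.5. No miR396 site was called at a score of at most 3 or by the first 10 bases alone, so a chance match stays possible. In other plants miR396 guides cuts in transcripts of growth-regulating factors, but whether this tag lies in such a transcript was not tested. Pairing was scored without bulges or gaps, so sites that need one can be missed. The 3 miR164 sites, which in other plants lie in NAC factors of organ boundaries and lateral roots, summed to 2640 root reads and 661 leaf reads, 4.72 times more in root (4.33 to 5.15). They did not move alike: TGCTTCTCCAATCCAATTGA had 2448 root reads and 432 leaf reads, while TGCTTCTCCATTTTCACCCC had 144 and 222, a leaf over root ratio of 1.30 (1.05 to 1.62).

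Cuts of 2 families linked to auxin response were higher in leaf. Sites of miR167, known to target activating auxin response factors, were higher in leaf by 6.28 times (4.66 to 8.61), with 371 reads against 50. These sites scored 4, the limit. No miR167 site was called at a score of at most 3 or by the first 10 bases alone, so a chance match stays possible. Sites of miR393, known to target auxin receptors, had 536 and 215 reads, a ratio of 2.11 (1.80 to 2.48). The miR160 site, known from repressing auxin response factors, had 231 leaf reads and 283 root reads in the tag GAGCCAGGCACGCTCAATAT, a ratio of 0.691 (0.578 to 0.825). That ratio became 0.899 (0.752 to 1.07) with reads scaled outside the 100 most abundant tags, so the miR160 difference did not hold up.

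Among the remaining families, miR172 (AP2-type factors of flowering and phase) was higher in leaf, with 531 reads against 135 and a ratio of 3.33 (2.75 to 4.05), most of it from TCAGGATTCTCATCTGTGTC with 341 against 19. For miR169 (NF-YA subunits) the reads were 137 and 40, a ratio of 2.90 (2.02 to 4.23), with 1.88 and 6.98 at its 2 sites. For miR168, which targets Argonaute itself, they were 103 and 58, a ratio of 1.503 (1.08 to 2.11). For miR403, whose target is another Argonaute, they were 325 and 227, a ratio of 1.21 (1.02 to 1.44). The 7 miR156 sites, in other plants in SPL factors of phase change, summed to 253 and 171 reads, a ratio of 1.25 (1.03 to 1.53), but the best site, TCTTCTGTCAACCAATTCTT, had 83 leaf reads and 97 root reads and turned the ratio to 0.724 (0.533 to 0.981). The intervals of miR319, with 39 and 43 reads, and miR395, with 25 and 28, included 1. The miR395 sum cannot be compared, however, because 1 of its 2 tags, with 23 leaf reads, lies in the stretch that the root list lacks. The other had 2 leaf and 28 root reads, a ratio of 0.0604 (0.00698 to 0.240).

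**Figure D3:**
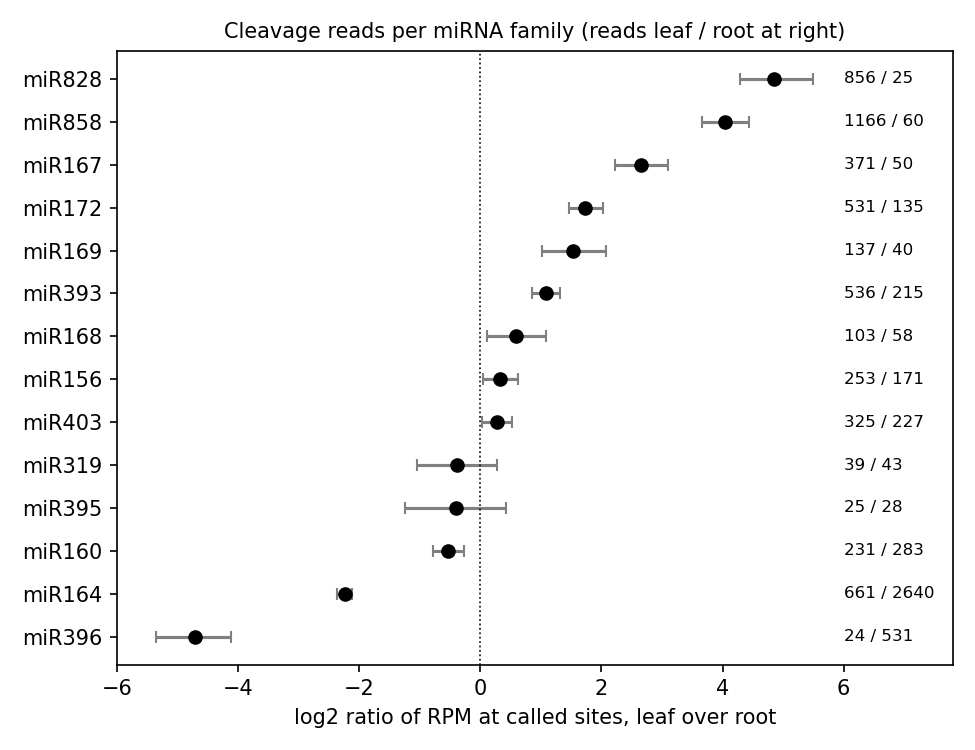
Log2 ratio of RPM at called sites, leaf over root (horizontal axis), for 14 miRNA families, with exact conditional binomial 95% intervals that cover counting error only; leaf and root reads stand at the right. The miR395 value includes a tag that the root list could not hold. miR828 at 4.86 and miR858 at 4.04 lie furthest towards leaf, miR396 at -4.71 and miR164 at -2.24 furthest towards root.

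In all, 9 families had intervals above 1, 3 below and 2 that included 1, and the median log2 ratio was 0.46. Scaling outside the 100 most abundant tags added 0.38 to each log2 ratio; the counts then were 9 and 2. Without the miR395 tag that the root list could not hold they were 9 and 4.

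Under these settings a further 9 families had a site only by the first 10 bases of the tag, a search that also called 2 of the 5 lineage controls in root and 0 in leaf. It called 17 families in leaf and 15 in root, where shuffled panels gave a mean of 7.25 and 6.39 and up to 14 and 12, so single tags of this kind can be chance. The best such tag of miR166, known to target class III HD-ZIP factors of vasculature and polarity, was CCTGGTCCGGATTCGGTTGG with 522 leaf reads and 514 root reads, a ratio of 0.859 (0.759 to 0.973). Scaling outside the 100 most abundant tags, which adds 0.38 to a log2 ratio, would turn its direction, so none is read from it. For miR171 the best tag was GGCTCAATCACCAGCTCTCT with 73 and 48. The tasiARF tag AGGTCAAGGAAGTTGGTGAC had 1924 leaf reads and 0 root reads, but with a window of 5 nucleotides tasiARF, like miR394, had a site paired over nucleotides 1 to 20 in both libraries. Leaf and root reads of the best tag were 86 and 3 for miR530, 0 and 65 for miR394, 5 and 45 for miR2111, 0 and 17 for miR827, 11 and 2 for miR399, and 10 and 2 for the miR482 and miR2118 family. The other 8 families had no called tag of either kind, though looser settings called some of them, such as miR2950 in root with the window of 5.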

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

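The tests below were chosen after the abundant tags had been seen, except those of the downstream fungal-type rRNA words and of tags upstream of the cut sites pooled over families, whose outcomes were predicted beforehand.

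Root held a signal outside the miRNA comparison: a tag at the start of a fungal-type large-subunit rRNA had 7814 reads in root and 45 in leaf. It equalled 13.1% of the reads of the plant 25S start tag in root and 0.00651% in leaf, a root over leaf ratio of 2014. That argues against misread copies of the plant tag, which would keep a similar ratio in both libraries. The ratio rests on the same counts that raised the question. It cannot exclude a variant of the plant rRNA whose level differs between the organs. Reads of fungi in the root sample are a candidate source: of 49 fungal-type words further downstream, 30.6% were listed in root and 2.04% in leaf, 15 times more. These were 15 words with 36 reads in root and 1 word with 2 reads in leaf, so the size of the difference is uncertain. Of 98 fungal-type 5.8S words, 9.18% were listed in root and 3.06% in leaf. Whether such fungi live in the root, lie on its surface or entered later stays open, and the sequences rest on general knowledge, with no genome to match.

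In leaf a single plastid 23S rRNA start tag took 6.87% of all reads, and nuclear rRNA starts were also high in RPM. PCR of single tags as the whole cause is argued against, since the other tags of the 18S and 25S start stretches were also higher in leaf, 8.32 times in RPM (7.99 to 8.67). For the plastid part, plastid RNA of green tissue may be the source, as rbcL and psbA tags had 298 leaf reads and 1 root read, a ratio of 252 (44.9 to 9992). That ratio rests on psbA, with 294 leaf reads, as rbcL had only 4 leaf reads and 0 root reads. For the nuclear part, less complete rRNA removal from leaf RNA cannot be told apart from an organ difference: the 18S and 25S stretches were 19.5 and 9.68 times higher in leaf but 5.8S only 1.07 times, and a 25S stretch further downstream 3.91 times (3.66 to 4.18).

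Cleavage reads were higher in leaf for some families and in root for others. Scaling of the libraries as the whole cause is argued against, because the intervals furthest towards leaf (miR828) and towards root (miR396) lay 8.404 apart on the log2 scale, a distance that any scaling leaves as it is. Target transcript level stays open for the families together: tags that start 2 to 7 bases upstream of the cut, and so come from RNA not cut there, had the pooled leaf over root ratios predicted for it, 1.58 (1.21 to 2.07) for families higher in leaf, below the 3.69 (3.44 to 3.96) of their cleavage reads, and 0.152 (0.0879 to 0.249) for those higher in root, beside 0.224 (0.208 to 0.241), but families weigh differently in these sums, and the intervals included 1 without miR172, at 1.26 (0.935 to 1.72), and without miR396, at 0.611 (0.275 to 1.32). Upstream tags are themselves ends of cut or decaying RNA, so they do not measure transcript level directly, and the site calls depended on them. Transcript level may account for differences of single families. Upstream ratios were 0.0577 (0.0206 to 0.131) for miR396, with 6 leaf and 88 root reads, and 3.26 (1.79 to 6.36) for miR172, with 54 and 14. They were 6.35 (1.48 to 57.2) for miR168, with 15 and 2, and at least 5.32 for miR858, with 25 and 0. The upstream ratio of miR393 pointed the other way from its cleavage reads, with 16 leaf and 36 root reads and 0.376 (0.195 to 0.695). These families were picked after the upstream counts had been seen, because their intervals excluded 1. Upstream intervals of the other families higher in 1 organ included 1, so the single-family values are descriptive. The organ's miRNA level was not measured and stays open.

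Tags with 11 or more bases of a sequencing adapter made 4.60% of leaf reads and 1.23% of root reads. A tag equal to the first 20 bases of mature miR159 had 564 reads in leaf and 227 in root.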

How the results depend on the processing

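Alternatives planned before the data were examined and 7 added afterwards were compared with the values above; the cause of a shift was not tested. Reads per distinct tag, leaf over root, fell from 1.92 to 1.69 with tags of at least 2 reads and 1.47 without the 100 most abundant tags.

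With tags of at least 2 reads, 18.5% of leaf and 16.6% of root tags were shared, with 55.0% and 34.4% of reads. With at least 5 reads these were 20.4%, 24.98%, 64.2% and 43.2%. Thinned to the same number of reads, 23.2% of leaf tags, 13.1% of root tags and 30.1% of root reads were shared. Without the stretch that the root list lacks (added), leaf had 22.9% of tags and 56.7% of reads shared.

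The ratio of expected to other starts was 2.54 in leaf and 1.89 in root at a score of at most 3, 1.37 and 1.53 at most 5, 2.96 and 2.82 with tags of at least 2 reads, and 2.23 and 1.71 with first 10 bases alone (added). Counting distinct tags turned it to 0.884 and 0.914. The real panel ranked above all 100 shuffled panels in the other settings. A miRNA with no spanned site at a given limit was searched by its first 10 bases. The score limit therefore also changed the kind of words, with 212 words at a score of at most 3 and 133 at 4, and does not test stricter pairing alone.

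Families called ranged from 10 to 17 in leaf and from 8 to 17 in root, the 8 at a score of at most 3; each count exceeded all shuffled panels, though 1 of the 5 lineage controls was called in root at a score of at most 5 and 1 in leaf with a window of 5 nucleotides. Families below 1 were 5 with the best site only and 5 with a window of 5 nucleotides (added), against 3. For single families, miR395 went from -0.40 to -4.05 without its tag in the stretch that the root list lacks (added), and miR156 turned to -0.47 with the best site only. miR858 went from 4.04 to 6.15 at a score of at most 3 and 5.803 with the best site only, which moved miR172 from 1.73 to 3.92. The best site only also moved miR169 from 1.54 to 0.91, and a window of 5 nucleotides (added) moved miR396 from -4.71 to -3.97. Of 94 such values 17 moved towards leaf, 12 of them by scaling alone, and 4 towards root. Under every setting that gave a value, families kept above 1 were 8 (miR167, miR168, miR169, miR172, miR393, miR403, miR828, miR858) and below 1 were 2 (miR164, miR396); miR167 and miR396 had no site at a score of at most 3.

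Not run were the window of 20 nucleotides, which tags of 20 bases cannot span, the first 20 bases of a tag, which are the whole tag, and the gene list alternatives. No paired analysis was possible because each group has 1 sample. Depth limits low families: root miR828 and miR858 rest on 25 and 60 reads.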

Other observations

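A tag equal to the start of mature miR159 was listed in both libraries, and which RNA it came from was not tested. Of 39 panel miRNAs, 8 of the 38 others had any tag equal to their first 20 bases, with at most 12 reads in leaf (miR168) and 3 in root (miR162). The miR159 tag had 564 and 227 reads, 2.102 times more RPM in leaf (1.799 to 2.46). miR159 itself, which in other plants cuts GAMYB-type transcripts, had 12 leaf reads at the expected start of its site words against a mean of 35.6 at other starts, and 24 against 24.0 in root.

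Within some families, single sites had unlike leaf over root ratios. The miR156 tag TCTTCTGTCAGACCAAACAA had 116 leaf and 18 root reads, a ratio of 5.45 (3.30 to 9.52), while TCTTCTGTCATCGTCGCCAT had 6 and 26, a ratio of 0.195 (0.0657 to 0.485). Of the miR172 sites, TCAGGATTCTCTTCTCCCAA had 101 and 81 reads, a ratio of 1.06 (0.780 to 1.43), beside 15.2 (9.58 to 25.5) for the most frequent one.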
